A study of Mus musculus with 18 samples.

How the data were processed

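Plateable cryopreserved hepatocytes of male CD-1 mice were treated with PBS, an siRNA against Ttr, 1 of 2 REVERSIR oligonucleotides, or the siRNA with either, and total RNA was sequenced. The deposited files hold 1 table of raw read counts per library for 37991 Ensembl genes. Per the submitters' processing notes, reads were aligned with STAR to the mouse build NCBIM37 and analysed with DESeq2, with no versions given. The counting tool, the strand of counting and any filter are not given in the sources used here. The counts deposited by the authors were whole numbers with library totals from 1755819 to 10145265, and replicates were not pooled. Gene symbols, types and positions came from the annotation of the same build for 37205 gene identifiers, and from the deposited tables for 49 more. As the strand of counting is not stated, values of genes that overlap others, as small nucleolar RNAs within host genes often do, are uncertain.

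The authors also deposited 5 tables of DESeq2 results, each comparing a treatment with PBS for 18218 genes. In them the authors gave a mean signal per gene over libraries after division by size factors, a log2 fold change with its standard error, a Wald score, and a p-value with its adjusted value. The largest standard error in these tables was 0.110, so that the deposited log2 fold changes look shrunken. They were not used to choose any gene. At an adjusted p under 0.05 the deposited tables listed 457 genes for siRNA, 212 for scrambled REVERSIR, 169 for TTR REVERSIR, 251 for siRNA + scrambled REVERSIR and 201 for siRNA + TTR REVERSIR. Of these, 231, 41, 60, 35 and 62 were also called here. The authors' log2 fold changes of Ttr were −1.85, 0.0042, 0.17, −1.94 and −0.06 in the same order.

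Libraries were grouped by the sample titles, 3 per group. The file of siRNA + scrambled REVERSIR replicate 2 carries another replicate number in its name, and the title was followed. The samples table, the 12 comparisons and their tests, the gene lists, the rule for naming genes and a first set of alternatives were fixed before the data were examined. Further alternatives, and the tests of technical and other explanations except the splits, were framed after the data had been seen. Genes were kept by filterByExpr of edgeR by group, which left 11153. All 18 libraries were fitted together with edgeR quasi-likelihood models after TMM scaling, with the group as the only term, so that 12 residual degrees of freedom estimate the spread. P-values were adjusted by Benjamini-Hochberg over the 11153 genes, with 0.05 as the threshold. The tests were 11 comparisons of 2 groups and the interaction of siRNA with the sequence of the REVERSIR, which is 12 comparisons in all. Standard errors were computed from the quasi-likelihood F statistic and the log2 fold change. Values per library are CPM after TMM scaling, with a prior count of 2 where the logarithm was taken. For Ttr, exact two-sided permutation tests of the CPM of 3 libraries against 3 were also run, which cannot go below p = 0.1.

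Gene lists were tested by camera on voom values with a preset correlation of 0.01 and again with an estimated correlation, and by fry, with adjustment over 216 tests of 18 lists. The lists were retinol and thyroid hormone handling, hepatocyte secreted proteins and identity, interferon response, acute phase and inflammation, p53 response, ER stress and integrated stress response, xenobiotic metabolism, RNA interference machinery, asialoglycoprotein receptor and endolysosome, cholesterol and fatty acid synthesis, peroxisome proliferator response and fatty acid oxidation, oxidative stress and heat shock, cell cycle, mitochondrially encoded mRNAs, and markers of Kupffer cells and macrophages, liver endothelium, stellate cells and fibroblasts, and cholangiocytes. Of 373 symbols in the lists, 1 matched no gene. Genes called in siRNA against PBS were followed as lists into the 3 comparisons that share no library with it, beside 10000 random lists matched on expression.

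The rule for naming genes took Ttr in every comparison. For each comparison of 2 groups it took, among genes past 0.05 with a mean log2 CPM of at least 1 and groups that do not overlap, the 12 with the highest and the 12 with the lowest log2 fold change. Where fewer than 5 genes passed, all of these were named, and the 5 others with the smallest p were given as values. From each list it took up to 4 members past 0.05 with the smallest p, or else up to 2 as values, and for the interaction the 10 genes with the smallest p. List members that did not pass are given as values for siRNA against PBS. Some values that this rule takes are not reported here.

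The guide sequence is not given in the sources used here. Every 7-base stretch of the longest Ttr transcript was therefore compared by two-sided rank-sum tests between genes with and without it in an annotated 3' UTR, and genes with no annotated 3' UTR were not searched. The stretch with the smallest p among those whose genes were lower in siRNA against PBS was tested in the 3 comparisons that share no library with it, again within 100 strata of A and T content and length of the 3' UTR, with standard errors from 1000 bootstraps.

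Each result except the short matches was recomputed with edgeR on DESeq2-style size factors, with library totals alone, with no filter beyond 1 count in total, with a stricter filter of a mean of at least 1 CPM, with a replicate block, and leaving out each library in turn. DESeq2 was run for gene counts and single genes only. The fit of the compared groups alone was run for these and for the lists. For the lists the estimated correlation was an alternative, and for the siRNA-changed genes a stricter threshold. The short matches had the stricter filter, 6-base and 8-base stretches and genes matched on 3' UTR length. Alternatives chosen after seeing the data were leaving out PBS replicates 1 and 2 together, the log2 share of mitochondrial ribosomal RNA as a covariate, leaving ribosomal RNA genes and Lars2 (with AY036118 and Gm15564) out of the counts, a correction for GC content and transcript length per library, and the strata of A and T content. In every comparison of groups of 3, the 10 splits of the 6 libraries were refitted, and 100 splits were drawn for the interaction.

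The procedure was tested on negative binomial counts simulated from the mean expression, library sizes and dispersions of these libraries, in which known genes were changed in 1 group. In siRNA against PBS 40% of genes changed by 0.5 on the log2 scale were recovered, 81.6% at 1, 98% at 1.5 and 92% at 2. In siRNA + TTR REVERSIR against siRNA the shares were 67.3%, 95.9%, 100% and 95.9%, and between the 2 groups with siRNA and an oligonucleotide they were 63.3%, 90% at 1, 93.9% and 98%. Unchanged genes made up 5.68%, 5.05% and 8.91% of those called. The libraries were drawn independently, without the deviation that PBS replicates 1 and 2 have in common. These shares therefore do not give the rate of false calls in the real comparisons with PBS. In the search for short matches, run on log2 fold changes shuffled over genes, a shift of −0.1 was found in 5 of 5 runs and a shift of −0.05 in 3 of 5. The shifted stretches were carried by fewer genes than the one selected in the data, and shuffling removed any trend with A and T content. These rates therefore do not describe the search in the data. The median biological coefficient of variation was 6.51%, and the lowest chi-square per degree of freedom between replicates was 2.24, which is above counting error. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No column of the count files was left unused, and no library was left out.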

Results

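RNA sequencing was carried out on total RNA from plateable cryopreserved hepatocytes of male CD-1 mice, 18 libraries in 6 groups of 3. The groups were a vehicle control (PBS), an siRNA against transthyretin (Ttr), a scrambled REVERSIR, a TTR REVERSIR, the siRNA with the scrambled REVERSIR, and the siRNA with the TTR REVERSIR. Transthyretin is the liver-secreted carrier of thyroxine and, with retinol-binding protein, of retinol. A REVERSIR is a short synthetic oligonucleotide complementary to the guide strand of an siRNA, made to bind that strand and release the target from silencing. The scrambled oligonucleotide serves as the control of the same chemistry for the sequence. The design asks how far each treatment changes Ttr and the other transcripts of the hepatocyte, and whether the TTR REVERSIR gives Ttr back.

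Total counts per library ran from 1755819 to 10145265. The group means ± SD (n = 3) were 5495800 ± 1475700 for PBS, 5981600 ± 1813500 for siRNA, 2403100 ± 585680 for scrambled REVERSIR, 4209300 ± 2093800 for TTR REVERSIR, 8078300 ± 2443500 for siRNA + scrambled REVERSIR and 7554500 ± 1412600 for siRNA + TTR REVERSIR. Libraries of the same group had Spearman correlations of log2 CPM (counts scaled by the effective library total) between 0.980 and 0.995, with a median of 0.992, against a median of 0.989 for libraries of different groups. On principal components 1 and 2 of 500 genes, with 22.2% and 16.9% of the variance, scrambled REVERSIR replicates 3 (−14.3, −22.7) and 1 (16.3, −7.12) lay farthest from the centre, followed by PBS replicates 2 (−12.2, 10.7) and 1 (−12.1, 4.38). By the share of mitochondrial ribosomal RNA, PBS replicates 1 and 2 stood apart from the other 16 libraries. The 2 ribosomal RNAs of the mitochondrion took 24.34% (Wilson 95% interval 24.31% to 24.37%) and 24.08% (24.05% to 24.12%) of their counts. The share was 5.45% (5.425% to 5.47%) in PBS replicate 3 and ran from 1.69% to 9.56% over all of the other 16 libraries. These intervals cover counting error only. Their 10 most abundant genes held 38.3% and 38.3% of the counts, against 14.5% to 20.9% elsewhere. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or animals. The p-values therefore measure differences against the spread between these libraries only, which may be technical.

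**Figure D1:**
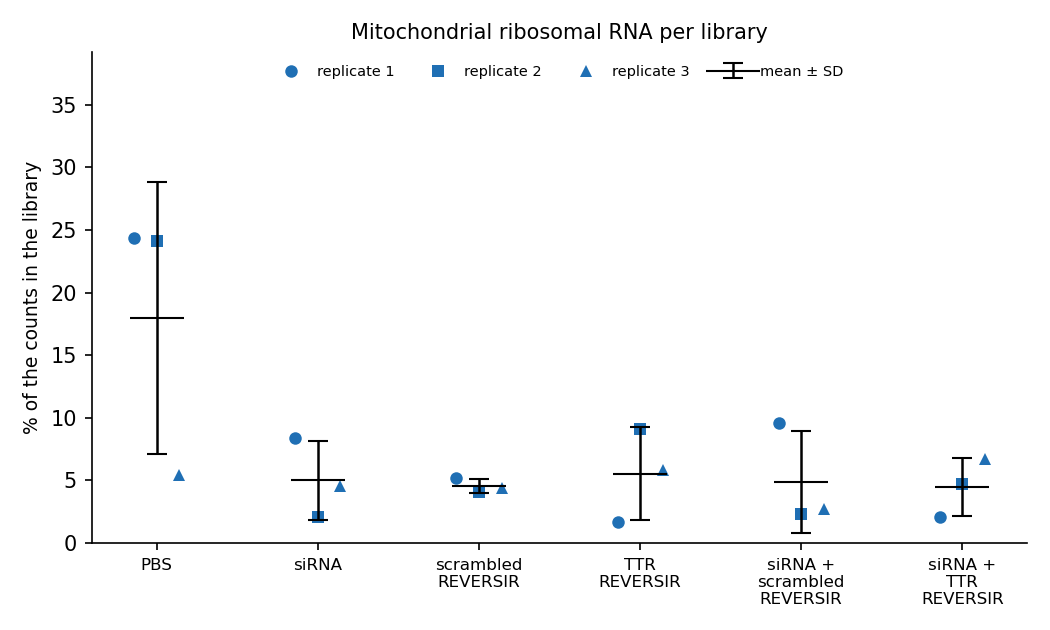
The share of counts from mitochondrial ribosomal RNA, in percent of all counts, is plotted for each of the 18 libraries by group, with symbols for the replicates and lines for the group mean ± SD. PBS replicates 1 and 2 lie at 24.3% and 24.1%, above the 1.69% to 9.56% of the other 16 libraries.

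Ttr mRNA (ENSMUSG00000061808, NCBIM37 chromosome 18, 20823751 to 20832825, plus strand) fell to 21.8% ± 1.72 (SD, n = 3) of the PBS mean with siRNA alone. It stood at 20.3% ± 0.0621 when the scrambled REVERSIR was present with the siRNA, and at 94.8% ± 10.1 when the TTR REVERSIR was present. Neither oligonucleotide given without siRNA moved Ttr past the test, with 101% ± 4.29 for the scrambled and 114% ± 14.2 for the TTR REVERSIR. In CPM the group means ± SD were 1111 ± 96.8 for PBS, 243 ± 19.1 for siRNA, 1118 ± 47.6 for scrambled REVERSIR, 1265 ± 157 for TTR REVERSIR, 226 ± 0.691 for siRNA + scrambled REVERSIR and 1054 ± 112 for siRNA + TTR REVERSIR. An exact two-sided permutation test gave p = 0.1 for siRNA against PBS, which is the smallest value that 3 libraries against 3 allow. Adjusted p-values for genes come from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment over 11153 genes, and values after ± beside a log2 fold change are standard errors of that fit.

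**Figure D2:**
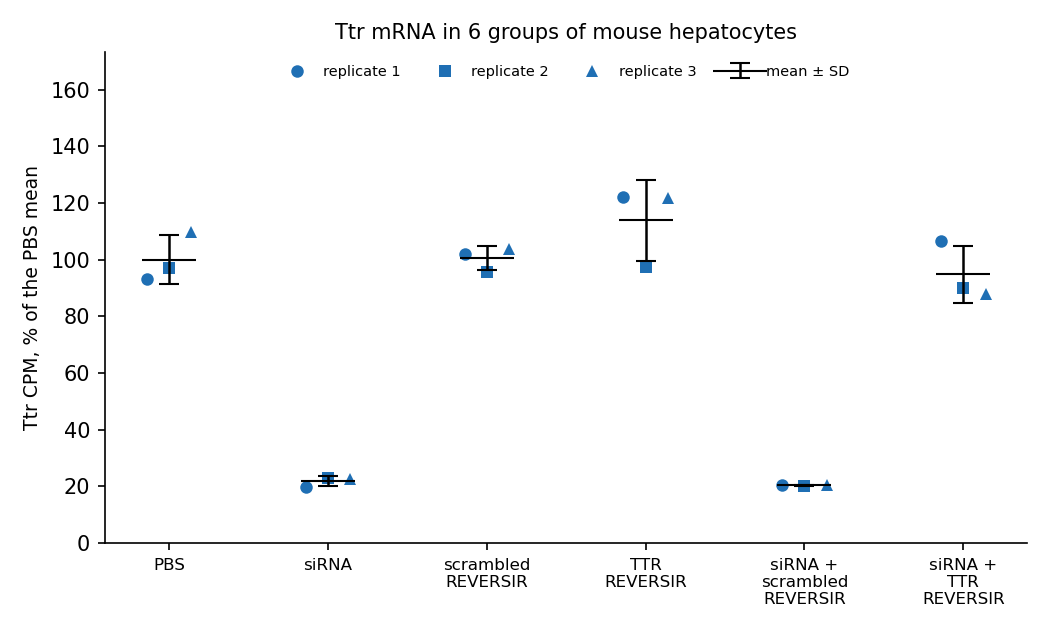
Normalized Ttr CPM, as percent of the PBS mean, are plotted for each of the 18 libraries by group, with symbols for the replicates and lines for the group mean ± SD. The 6 libraries with siRNA and no TTR REVERSIR lie between 19.8% and 22.8% of the PBS mean, and the siRNA + TTR REVERSIR group averages 94.8%.

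The siRNA was compared with PBS to measure silencing of Ttr and any change of other transcripts. Ttr changed by −2.19 ± 0.0938 on the log2 scale (95% interval −2.39 to −2.0, adjusted p = 5.66e-14), which is 4.58-fold lower. Among the other 291 genes past the threshold, Acaa1a, a peroxisomal thiolase of fatty acid oxidation, rose by 0.83 ± 0.15 (adjusted p = 0.0125). Tsfm, a mitochondrial translation elongation factor, rose by 1.00 ± 0.21 and the calcium-binding protein gene S100a6 by 0.78 ± 0.17. Transcripts that were lower included Trf, the plasma iron carrier transferrin (−0.56 ± 0.11, adjusted p = 0.0163), Patl1, an mRNA decapping factor (−0.73 ± 0.14), and Dynlrb1, a dynein light chain (−0.80 ± 0.16).

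By the lists fixed beforehand, 3 of the 20 measured xenobiotic metabolism genes were lower with siRNA than with PBS: the cytochrome P450 genes Cyp3a11 (−0.38 ± 0.077) and Cyp2c29 (−0.30 ± 0.068) and the bilirubin-conjugating Ugt1a1 (−0.54 ± 0.13). Of 23 interferon response genes, Isg15 (0.46 ± 0.099) and Irf7 (0.26 ± 0.069) were higher. The ER stress list had 2 of 22 members higher, the disulfide isomerase gene Pdia6 (0.32 ± 0.070) and Trib3 (0.39 ± 0.10), and Serpina7, encoding thyroxine-binding globulin, was higher by 0.41 ± 0.11. The RNA-editing gene Adar was higher by 0.32 ± 0.074. Hmox1 and Gclc of the oxidative stress list (−0.34 ± 0.092 and −0.26 ± 0.070) and Ccng1 of the p53 list (−0.25 ± 0.062) were lower. Of 7 measured mitochondrially encoded mRNAs, 4 were lower (mt-Co1, −0.45 ± 0.091; mt-Nd2, −0.54 ± 0.12; mt-Nd4, −0.52 ± 0.13; mt-Nd1, −0.41 ± 0.11), and 5 when adjusted over the list alone, with a list mean of −0.33. That list was called by camera (adjusted p = 0.00029), and adjusted p = 0.564 with an estimated correlation. Adjusted over the list alone, 5 retinol and thyroid genes (4 higher, 1 lower), 1 secreted protein gene (lower), 2 interferon genes (both higher), 4 acute phase genes (3 higher, 1 lower), 2 p53 genes (1 higher, 1 lower), 5 ER stress genes (3 higher, 2 lower), 3 xenobiotic genes (all 3 lower), 1 RNA interference gene (higher), 6 oxidative stress genes (3 higher, 3 lower) and 1 cell cycle gene (lower) passed. Of markers of other cell types, 2 of 6 for Kupffer cells and macrophages (both higher, list mean 0.26, camera adjusted p = 0.559), 1 of 10 for stellate cells and fibroblasts (lower) and 1 of 7 for cholangiocytes (higher) passed in the same way. These groups of genes were measured against a PBS group in which replicates 1 and 2 held 24.3% and 24.1% of counts in mitochondrial ribosomal RNA.

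In all, 292 of 11153 genes passed in siRNA against PBS, 113 higher and 179 lower, 15 of them by 2-fold or more. An unadjusted p under 0.05 was found for 2241 genes, where 558 would by chance, a number that holds for each of the 12 comparisons. With library totals alone as the scale, the median of all genes moved by 0.33, and 3819 of 3844 called genes were higher. Ttr alone was called without PBS replicates 1 and 2, a run chosen after seeing the data in which the lone PBS sample is assumed to vary like the other groups. Leaving out PBS replicate 1, 2 or 3 gave 1, 2 and 1365 genes, and leaving out siRNA replicate 1, 2 or 3 gave 62, 12 and 44. Of the 24 genes named by rule besides Ttr, 0 stayed called without PBS replicate 1, and DESeq2, which called 421 genes in all, called 5 of the 24. A fit of siRNA and PBS alone, which takes the spread from these groups only, called 1 gene, Ttr. The other named genes that were higher ran from 0.77 (Efha2) to 2.16 (Ccdc22, of the endosomal CCC complex) and include Snora68, RP24-323I5.2, BC002230, Kptn, Gm10119, Bad and Ssna1. The lower ones ran from −0.84 (Zfp825) to −1.71 (Rps15-ps2) and include Gm16869, Gm14295, Mup-ps22, Gm10033, Gm13835, Lipo1, Zfp930 and Gm13456. Rps15-ps2, Mup-ps22, Gm13835 and Gm13456 are annotated as pseudogenes, whose reads cannot be told with certainty from those of their parent genes, and the other Gm genes carry predicted names only. The value of the small nucleolar RNA Snora68 is uncertain as well.

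The siRNA with scrambled REVERSIR was compared with PBS to see whether a REVERSIR of another sequence leaves silencing in place. Ttr was lower by 4.91-fold (−2.30 ± 0.0939, adjusted p = 2.04e-14). Gpt, which encodes alanine aminotransferase, rose by 0.57 ± 0.10 (adjusted p = 0.012), Acaa1a by 0.69 ± 0.15, and the interferon-induced Isg15 by 0.42 ± 0.098. Trf (−0.56 ± 0.11), the RNA-binding protein gene Pcbp2 (−0.79 ± 0.18), Dynlrb1 (−0.79 ± 0.15), Patl1 (−0.69 ± 0.13) and Ireb2, an iron-responsive regulator of mRNAs (−0.69 ± 0.15), were lower. Mitochondrially encoded mRNAs had a mean of −0.18, with 5 of 7 lower and 1 higher adjusted over the list alone, called by camera (adjusted p = 0.0188), and adjusted p = 0.699 with an estimated correlation. With library totals alone that mean was 0.12 (camera adjusted p = 0.0427), where the median of all genes moved by 0.32. With the share of mitochondrial ribosomal RNA as a covariate, a run chosen after seeing the data, the mean was −0.0098 (adjusted p = 0.366). That share was highest in PBS replicates 1 and 2, so the covariate takes up part of any difference from PBS. The call was lost without PBS replicates 1 and 2 together (mean −0.15, adjusted p = 0.117), without PBS replicate 2 alone (mean −0.14, adjusted p = 0.0745) and without siRNA + scrambled REVERSIR replicate 3 (mean −0.12, adjusted p = 0.114). Beside the same share of mitochondrial ribosomal RNA in PBS replicates 1 and 2 (24.3% and 24.1%), the interferon list had a mean of 0.12 (1 of 23 higher, 3 higher adjusted over the list alone), with adjusted p = 0.00493 by camera and adjusted p = 0.71 with an estimated correlation. The interferon call was lost without PBS replicate 3 (mean 0.13, adjusted p = 0.139) and without siRNA + scrambled REVERSIR replicate 1 (mean 0.091, adjusted p = 0.0565).

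Here 68 genes passed, 23 higher and 45 lower, 9 by 2-fold or more, with 1975 at an unadjusted p under 0.05. DESeq2 called 201 genes and 4 of the 24 named by rule. A fit of the compared groups alone called 7 genes and 2 of the 24. With library totals alone the median gene moved by 0.32 and 3531 of 3557 called genes were higher. Leaving out PBS replicate 1, 2 or 3 gave 1, 5 and 1142 genes, leaving out siRNA + scrambled REVERSIR replicate 1, 2 or 3 gave 11, 1 and 3, and without PBS replicates 1 and 2 together Ttr was the 1 gene called. The remaining named genes were Fzd7, Trim6, Slc24a6, Timm13, Id3, Parp10, BC002230, RP24-323I5.2, 2310011J03Rik and 9130401M01Rik (0.54 to 1.06) among the higher, and Fam98b, Rybp, Rprd1a, Y_RNA, Gm16869, Mup-ps22, Gm13835 and Gm13456 (−0.76 to −2.11) among the lower. Mup-ps22, Gm13835 and Gm13456 are annotated as pseudogenes and Y_RNA has many copies, so their values are uncertain.

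Scrambled REVERSIR alone against PBS asks what the oligonucleotide chemistry does without an siRNA and without a matching sequence. Ttr was at 0.01 ± 0.0896 (95% interval −0.18 to 0.19, adjusted p = 0.98). Serpina7 rose by 0.65 ± 0.11 (adjusted p = 0.0208), the ER chaperone gene Hspa5 by 0.38 ± 0.082 (adjusted p = 0.0471), the transferrin receptor gene Tfrc by 0.37 ± 0.084 and S100a6 by 0.83 ± 0.19. Car3, a carbonic anhydrase, was lower by −0.60 ± 0.10 (adjusted p = 0.0208), as were Gnmt of methionine metabolism (−0.56 ± 0.11), the hepatic uptake transporter gene Slco1b2 (−0.56 ± 0.11), Cyp2c29 (−0.36 ± 0.070), Cyp3a11 (−0.36 ± 0.077) and the heme oxygenase gene Hmox1 (−0.50 ± 0.097). Camera called the secreted protein list (mean −0.083, 0 of 23 past the threshold and 3 adjusted over the list alone, 1 higher and 2 lower, adjusted p = 0.0337), xenobiotic metabolism (mean −0.076, 2 of 20 lower and 7 lower adjusted over the list alone, adjusted p = 0.0363) and ER stress (mean 0.082, 1 of 22 higher and 2 higher adjusted over the list alone, adjusted p = 0.0363). These came to adjusted p = 0.699, adjusted p = 0.564 and adjusted p = 0.591 with an estimated correlation. With library totals alone the first and second means turned to 0.20 and 0.21, where the median of all genes moved by 0.29. For the secreted proteins the call was lost without PBS replicate 3 (mean −0.075, adjusted p = 0.0608), without scrambled REVERSIR replicate 1 (mean −0.077, adjusted p = 0.0916) and without replicate 3 (mean −0.064, adjusted p = 0.0734). Xenobiotic metabolism lost it without PBS replicate 3 (mean −0.079, adjusted p = 0.0744) and without scrambled REVERSIR replicate 1 (mean −0.044, adjusted p = 0.0916), and ER stress without PBS replicate 1 (mean 0.049, adjusted p = 0.139), scrambled REVERSIR replicate 2 (mean 0.062, adjusted p = 0.132) or replicate 3 (mean 0.085, adjusted p = 0.0769). Without PBS replicates 1 and 2 together all 3 calls were lost, with means of −0.087 for secreted proteins (adjusted p = 0.0721), −0.0047 for xenobiotic metabolism (adjusted p = 0.0504) and 0.048 for ER stress (adjusted p = 0.193). ER stress was also lost with no filter on low counts (mean 0.099, adjusted p = 0.48) and came to 0.024 with the share of mitochondrial ribosomal RNA as a covariate (adjusted p = 0.354). PBS replicates 1 and 2, with 24.3% and 24.1% of mitochondrial ribosomal RNA, were the controls for these lists as well.

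A total of 47 genes passed, 13 higher and 34 lower, 2 by 2-fold or more, with 1636 at an unadjusted p under 0.05. DESeq2 called 188, 86 of them higher, and 20 of the 24 named by rule. The compared groups fitted alone gave 7 genes, with 3 of the 24 among them. Library totals alone moved the median gene by 0.29 and called 1580 genes, 1564 of them higher. With PBS replicate 3 as the only control, the 47 called genes had a median size of 0.26 on the log2 scale, against 0.52 with all 3 controls. Leaving out PBS replicate 1, 2 or 3 gave 0, 0 and 749 genes, and leaving out scrambled REVERSIR replicate 1, 2 or 3 gave 43, 0 and 0. Other named genes were Snhg5, Tbc1d2b, Acnat2, Tagln2, Mia2, Cxcl16, Mkrn1 and Srsf1 (0.34 to 0.87), and Rprd1a, Mup16, Patl1, Cck, Med21, Rpl41, Wrnip1, Gm13436 and Gm13456 (−0.55 to −1.79), of which Mup16 has near-identical copies and both Gm genes are annotated as pseudogenes, so their values are uncertain.

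TTR REVERSIR alone against PBS asks what the siRNA-directed oligonucleotide does with no siRNA to bind. Ttr was at 0.19 ± 0.0892 (adjusted p = 0.294, and 0.0681 adjusted over the 12 comparisons of Ttr). With library totals alone it was at 0.47 (adjusted p = 0.0254), where the median of all genes also moved by 0.31. Car3 was lower (−0.69 ± 0.099, adjusted p = 0.00357), as were Mapk3, which encodes the kinase ERK1 (−0.71 ± 0.14), Trf (−0.49 ± 0.11), the acute phase gene Orm2 (−0.39 ± 0.083) and Cyp2c29 (−0.30 ± 0.069). Urod, an enzyme of heme synthesis, rose by 0.71 ± 0.14 (adjusted p = 0.0357) and the pro-apoptotic Bax by 0.39 ± 0.089. Ndufa9 and Atp5k, which encode a subunit of respiratory complex I and one of the ATP synthase, were higher (0.58 ± 0.12 and 0.63 ± 0.15). Ndufa12, of complex I, and Atpif1, an inhibitor of the ATP synthase, were lower (−0.65 ± 0.13 and −0.65 ± 0.15). Mitochondrially encoded mRNAs had a mean of −0.31, with mt-Co1 past the threshold (−0.42 ± 0.091) and 5 of 7 lower when adjusted over the list alone. Camera gave adjusted p = 2.27e-05 for that list, and adjusted p = 0.564 with an estimated correlation. PBS replicates 1 and 2 carried 24.3% and 24.1% of mitochondrial ribosomal RNA in this comparison too.

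The number past the threshold was 78, 38 higher and 40 lower, 10 by 2-fold or more, with 1825 at an unadjusted p under 0.05. DESeq2 called 173 genes and 3 of the 24 named by rule, and library totals alone called 2883, of which 2852 were higher. The compared groups fitted alone gave 0 genes by edgeR. With PBS replicate 3 as the only control, the 78 called genes had a median size of 0.26 on the log2 scale, against 0.58 with all 3 controls. Leaving out PBS replicate 1, 2 or 3 gave 1, 0 and 978 genes, and leaving out TTR REVERSIR replicate 1, 2 or 3 gave 0, 375 and 1. Further named genes were Snora68, BC002230, Alkbh2, Aarsd1, Dpm2, Mdp1, Parp10, 9130401M01Rik and the pseudogene Gm9816 (0.58 to 2.10), and RNaseP_nuc, Patl1, Mup16, Mup-ps22, Gm16869, Gm15801, Gm14166 and Gm13835 (−0.64 to −1.91), of which Mup16 has near-identical copies and Mup-ps22, Gm15801, Gm14166 and Gm13835 are annotated as pseudogenes. Their values and that of the small nucleolar RNA Snora68 are uncertain.

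The siRNA with TTR REVERSIR was compared with PBS to see how near the treated cells come to untreated ones. Ttr differed by −0.08 ± 0.0890, with a 95% interval of −0.26 to 0.11 and adjusted p = 0.706. Neat1, the long non-coding RNA of nuclear paraspeckles, rose by 1.91 ± 0.38 (adjusted p = 0.024), Ndufb2 of complex I by 1.02 ± 0.22, Slc25a38, a mitochondrial carrier needed for heme synthesis, by 1.04 ± 0.24 and the splicing factor gene Srsf2 by 0.75 ± 0.18. Trf (−0.63 ± 0.11, adjusted p = 0.0217), the ER disulfide isomerase gene Pdia3 (−0.77 ± 0.17, adjusted p = 0.0415), the immunophilin gene Fkbp1a (−0.97 ± 0.22), Max, the partner of Myc (−0.62 ± 0.12), and Sel1l of ER-associated degradation (−0.32 ± 0.067) were lower. No gene list was called in this comparison, and mitochondrially encoded mRNAs had a mean of −0.04 (camera adjusted p = 0.444), beside the same 24.3% and 24.1% of mitochondrial ribosomal RNA in PBS replicates 1 and 2.

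Against PBS, 88 genes passed with siRNA + TTR REVERSIR, 39 higher and 49 lower, 13 by 2-fold or more, with 1974 at an unadjusted p under 0.05. DESeq2 called 242 and 5 of the 24 named by rule, and library totals alone moved the median gene by 0.33 and called 4089, 4067 of them higher. The compared groups fitted alone gave 1 gene. With PBS replicate 3 as the only control, the 88 called genes had a median size of 0.24 on the log2 scale, against 0.53 with all 3 controls. Leaving out PBS replicate 1, 2 or 3 gave 0, 1 and 1151 genes, and leaving out siRNA + TTR REVERSIR replicate 1, 2 or 3 gave 0, 23 and 6. Among the remaining named genes were Ccdc22, Snora68, SNORD94, SNORA32, Tsfm, Dnalc1, RP24-323I5.2 and Rpl38-ps2 (0.88 to 2.16), and Patl1, Brwd3, Tmem188, Pigt, Gm16869, Gm13436, Gm13456 and Mup-ps22 (−0.53 to −1.85), with Rpl38-ps2, Mup-ps22, Gm13436 and Gm13456 uncertain as annotated pseudogenes and Snora68, SNORD94 and SNORA32 as small nucleolar RNAs.

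Because the 5 treatments share 3 PBS libraries, chance values of those libraries enter all 5 comparisons. Serpina1c, Patl1, Gm13436, B2m, Car3 and Med21 were lower in each of the 5, and 0 such genes were found in 20 simulations of counts with no effect and shared controls. The simulations drew the 3 PBS libraries independently, without the deviation that PBS replicates 1 and 2 have in common. The 0 in simulation therefore does not weigh against that deviation as a source of these 6 genes. B2m, the light chain of class I histocompatibility molecules, was lower by −0.58 ± 0.11 with siRNA and by −0.52 ± 0.11 with TTR REVERSIR. Serpina1c, 1 of several near-identical antitrypsin genes, was at −0.61 ± 0.13 with siRNA, and its reads cannot be assigned with certainty. B2m and Serpina1c fall outside the naming rule and were chosen after their values were seen. Across genes, which are not independent replicates, log2 fold changes of siRNA and of scrambled REVERSIR against PBS correlated with r = 0.626, where shared controls alone gave 0.531 in simulation. The same value was 0.744 (simulated 0.598) for TTR REVERSIR, 0.788 (simulated 0.657) for siRNA + scrambled REVERSIR and 0.78 (simulated 0.653) for siRNA + TTR REVERSIR. No 2 treatments were compared with separate parts of the 3 controls. The genes called against PBS kept their sign in 96.2% to 100% of cases when PBS replicate 3 alone served as the control, with the median size for siRNA falling from 0.41 to 0.20, a value that is not independent since PBS replicate 3 took part in the selection.

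The siRNA with TTR REVERSIR against siRNA alone tests directly whether the REVERSIR restores the target. Ttr was 4.34-fold higher (2.12 ± 0.0934, adjusted p = 1.17e-13), and its libraries did not overlap those of siRNA alone. No other of 11153 genes passed in edgeR, where 667 had an unadjusted p under 0.05, and DESeq2 called 15 genes. Without the filter on low counts edgeR called 21. Dropping the filter lowered p-values at nearly the same fold, so counts without it are not comparable with the others. In TTR REVERSIR against scrambled REVERSIR, Serpina7 went from −0.66 (adjusted p = 0.0193 by edgeR) to −0.65 (adjusted p = 5.0e-13). The 5 other genes with the smallest p had values of 0.33 for Ccng2, 0.30 for Rg9mtd1, −0.44 for Osgin1, −0.44 for Serpina7 and −0.35 for the connexin gene Gjb2, all with adjusted p = 0.556. Mitochondrially encoded mRNAs averaged 0.28 (adjusted p = 1.24e-05 by camera, and adjusted p = 0.548 with an estimated correlation). Acute phase genes averaged −0.12 (adjusted p = 0.00145, and adjusted p = 0.564 with an estimated correlation), ER stress genes −0.093 (adjusted p = 0.00251, and adjusted p = 0.548 with an estimated correlation) and p53 genes 0.088 (adjusted p = 0.0421, and adjusted p = 0.548 with an estimated correlation). Beside the acute phase genes, Kupffer cell and macrophage markers averaged −0.28, with 3 of 6 lower over the list alone, and were not called (camera adjusted p = 0.0811). Over the list alone 2 acute phase genes, 1 ER stress gene, 0 p53 genes and 0 mitochondrial mRNAs passed. Without siRNA replicate 2 the acute phase, ER stress and p53 calls were lost (means −0.096, −0.069 and 0.076, adjusted p = 0.054, 0.0579 and 0.185). They were also lost without siRNA + TTR REVERSIR replicate 2 for acute phase and p53 (means −0.078 and 0.083, adjusted p = 0.0791 for both), and without its replicate 3 for ER stress and p53 (means −0.075 and 0.061, adjusted p = 0.0545 and 0.164). The 95% interval lay within 2-fold for 94.3% of genes, and without siRNA replicate 3 the count was 2.

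Adding scrambled REVERSIR to the siRNA, against siRNA alone, asks whether an oligonucleotide that does not match the guide alters silencing. Ttr differed by −0.10 ± 0.0910, with a 95% interval of −0.29 to 0.09 (adjusted p = 1.00). Of all genes 0 passed in edgeR and 0 in DESeq2, with 415 at an unadjusted p under 0.05, below the 558 of chance. Without the filter on low counts edgeR called 33, of which 7 were higher. The smallest p belonged to Ppp1r3b, a regulator of glycogen synthesis (0.38 ± 0.077, adjusted p = 0.613), followed by Ccng2 (0.31), the small nuclear RNA U2 (−1.23), Serpina7 (−0.37) and AB041803 (0.87). Kupffer cell and macrophage markers, 6 of which were measured, averaged −0.40 (adjusted p = 0.0115 by camera, and adjusted p = 0.548 with an estimated correlation), and 3 passed when adjusted over the list alone. That call was lost without siRNA replicate 2 (mean −0.29, adjusted p = 0.0911) and without siRNA + scrambled REVERSIR replicate 1 (mean −0.37, adjusted p = 0.07). Acute phase genes averaged −0.15 (adjusted p = 2.09e-05, and adjusted p = 0.548 with an estimated correlation, 1 passing over the list alone) and mitochondrially encoded mRNAs 0.14 (adjusted p = 0.0179, and adjusted p = 0.699 with an estimated correlation). The mitochondrial call was lost without siRNA replicate 1 (mean 0.13, adjusted p = 0.0893) or 2 (mean 0.093, adjusted p = 0.233) and without siRNA + scrambled REVERSIR replicate 1 (mean 0.11, adjusted p = 0.118) or 2 (mean 0.11, adjusted p = 0.142). For 94.7% of genes the 95% interval lay within 2-fold.

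Between the 2 groups that received siRNA with an oligonucleotide, Ttr was 4.66-fold higher with the TTR than with the scrambled sequence (2.22 ± 0.0935, adjusted p = 4.05e-14). This comparison isolates the sequence of the REVERSIR in the presence of siRNA. No gene besides Ttr passed in edgeR, with 242 at an unadjusted p under 0.05, below the 558 of chance, and DESeq2 also called Ttr alone. Without the filter on low counts edgeR called 35. The next smallest p-values belonged mostly to small nucleolar RNAs, with uncertain values of 1.56 for AC150277.1, 1.14 for Snora68, 1.2 for Snord15a and 0.49 for SNORA12, beside −0.51 for Plekhg2 (smallest adjusted p = 0.817). Interferon genes averaged −0.068 (adjusted p = 0.00493 by camera, and adjusted p = 0.71 with an estimated correlation) and mitochondrially encoded mRNAs 0.14 (adjusted p = 0.0122, and adjusted p = 0.699 with an estimated correlation), with 0 members of either passing over the list alone. The interferon call was lost without siRNA + scrambled REVERSIR replicate 1 (mean −0.037, adjusted p = 0.178) or 3 (mean −0.012, adjusted p = 0.202) and without siRNA + TTR REVERSIR replicate 2 (mean −0.013, adjusted p = 0.808). The mitochondrial call was lost without siRNA + scrambled REVERSIR replicate 3 (mean 0.079, adjusted p = 0.281) and without siRNA + TTR REVERSIR replicate 3 (mean 0.061, adjusted p = 0.473). The 95% interval of the difference was within 2-fold for 95.6% of genes.

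TTR REVERSIR against scrambled REVERSIR, both without siRNA, compares the sequences of the oligonucleotides themselves. A pair of genes of thyroid hormone and retinol handling was lower with the TTR sequence: Serpina7, encoding thyroxine-binding globulin (−0.66 ± 0.11), and Aldh1a1, a retinal dehydrogenase (−0.63 ± 0.10), both with adjusted p = 0.0193. Serpina7 measured 175 ± 28.1 CPM (SD, n = 3) with the TTR and 274 ± 10 CPM with the scrambled sequence, against 175 ± 12.5 in PBS. Aldh1a1 measured 139 ± 7.49 and 215 ± 15.7 CPM, against 166 ± 18.1 in PBS. These were 2 of 17 measured members of the retinol and thyroid list, also adjusted over the list alone, and the list as a whole was not called (mean −0.062, camera adjusted p = 0.156). Ttr differed by 0.18 ± 0.0896 (adjusted p = 0.698). Values that did not pass were −0.47 for Hif1a (adjusted p = 0.182), 0.38 for Smox, 0.52 for Wrnip1 and 0.71 for Dpysl2. The secreted protein list averaged 0.093 (adjusted p = 0.00169, and adjusted p = 0.596 with an estimated correlation) and mitochondrially encoded mRNAs −0.18 (adjusted p = 0.000958, and adjusted p = 0.578 with an estimated correlation), both lost without TTR REVERSIR replicate 1 (means 0.058 and −0.074, adjusted p = 0.12 and 0.104), with 0 members passing over the list alone. Liver endothelial markers, which were not called, averaged 0.35 beside them (camera adjusted p = 0.187).

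The 2 calls depended on single libraries, in a comparison where scrambled REVERSIR replicates 3 and 1 were the farthest of the 18 libraries from the centre of the principal components. Serpina7 was no longer called without scrambled REVERSIR replicate 2 (adjusted p = 0.284) or 3 (adjusted p = 0.138), without TTR REVERSIR replicate 1 (adjusted p = 0.368) or 3 (adjusted p = 0.285), or with library totals alone (adjusted p = 1), and Aldh1a1 was lost in the same 5 runs (adjusted p = 0.284, 0.138, 0.0749, 0.285 and 1). In these runs the log2 fold changes lay between −0.65 and −0.59 for Serpina7 and between −0.68 and −0.58 for Aldh1a1. DESeq2 called both (adjusted p = 0.000219) and 3 genes in all, and 818 genes had an unadjusted p under 0.05. The count was 3 without scrambled REVERSIR replicate 1, 5 without TTR REVERSIR replicate 2, and 0 without any other single library of the 2 groups. The 95% interval lay within 2-fold for 84.9% of genes.

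**Figure D3:**
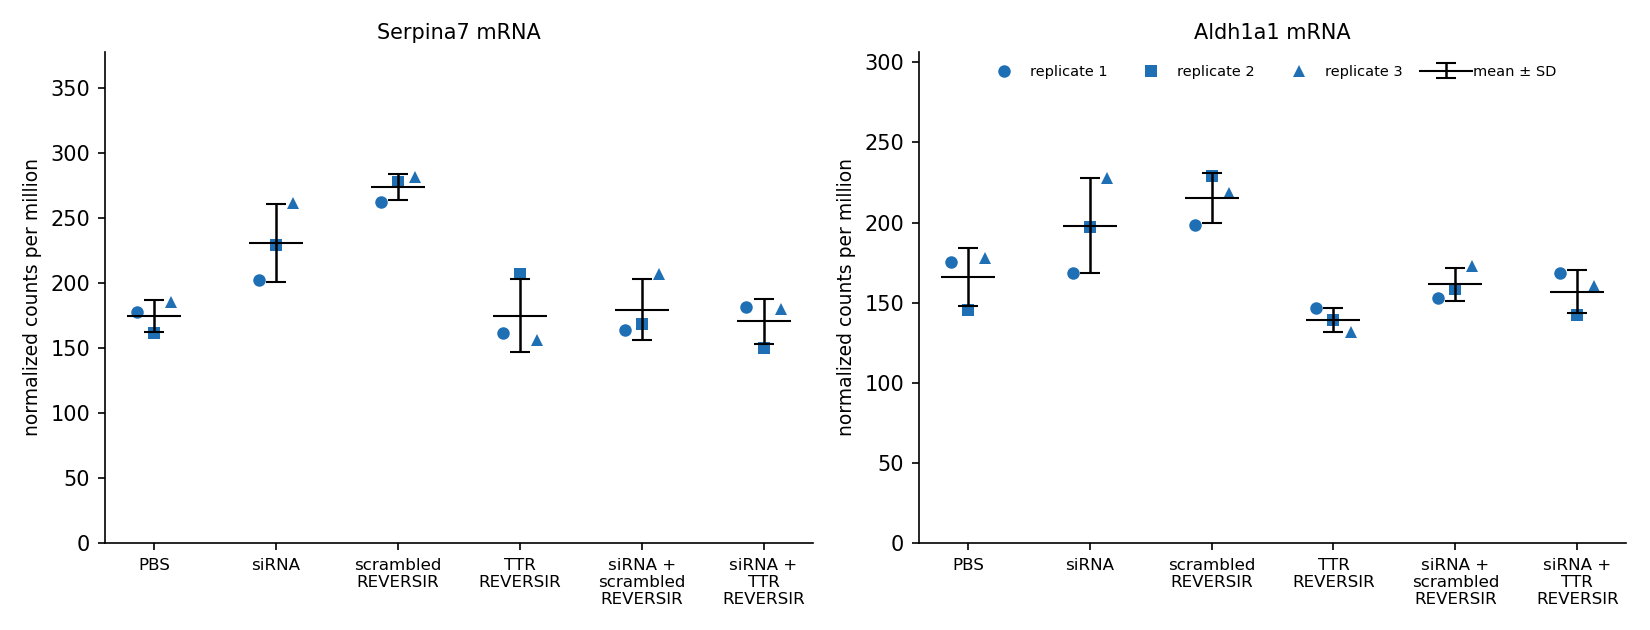
Normalized CPM of Serpina7 and Aldh1a1 are plotted for each of the 18 libraries by group, with symbols for the replicates and lines for the group mean ± SD. The scrambled REVERSIR group averages 274 for Serpina7 and 215 for Aldh1a1, and the TTR REVERSIR group 175 and 139.

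The siRNA in the presence of scrambled REVERSIR, against scrambled REVERSIR alone, measures silencing in libraries other than those of siRNA and PBS. Ttr was 4.94-fold lower (−2.30 ± 0.0943, adjusted p = 2.05e-14). Serpina7 was the 1 other gene past the threshold, at 180 ± 23.7 against 274 ± 10 CPM (−0.61 ± 0.11, adjusted p = 0.0369). The nucleolar methyltransferase gene Fbl had a value of 0.61 (adjusted p = 0.144), and H2-Q4 (0.41), Slc25a47 (0.44), Acnat2 (−0.58) and Tfrc (−0.36) did not pass either (adjusted p = 0.319). Interferon genes averaged 0.10 (adjusted p = 0.00363 by camera, and adjusted p = 0.699 with an estimated correlation, 0 passing over the list alone), which was lost without scrambled REVERSIR replicate 1 (mean 0.026, adjusted p = 0.478), a library far from the centre of the principal components, and without siRNA + scrambled REVERSIR replicate 1 (mean 0.071, adjusted p = 0.0539). The call of Serpina7 was lost without scrambled REVERSIR replicate 2 (adjusted p = 0.257) or 3 (adjusted p = 0.335), without siRNA + scrambled REVERSIR replicate 1 (adjusted p = 0.625) or 2 (adjusted p = 0.348), and with library totals alone (adjusted p = 1.00), while its log2 fold change in these 5 runs lay between −0.60 and −0.55. DESeq2 called both genes, 694 genes had an unadjusted p under 0.05, and 9 were called without scrambled REVERSIR replicate 1 against 1 or 2 without any other library.

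With TTR REVERSIR present, the siRNA was compared with TTR REVERSIR alone. Ttr was at −0.26 ± 0.0891 (95% interval −0.45 to −0.08), which is 1.2-fold lower. It did not pass over all genes (adjusted p = 1.00), with adjusted p = 0.0113 over the 12 comparisons of Ttr. No gene passed in edgeR or DESeq2, with 495 at an unadjusted p under 0.05, below the 558 of chance. Without the filter on low counts edgeR called 35, of which 31 were higher. The compared groups fitted alone and the mitochondrial rRNA share as a covariate each gave 1. Neat1 had a value of 1.66 ± 0.37, the small nucleolar RNA SNORA14 of 1.03 (uncertain), Gm16586 of 0.85, Gm14420 of 0.59 and Dleu2 of 1.11 (adjusted p = 0.451). Mitochondrially encoded mRNAs averaged 0.27 (adjusted p = 3.87e-07 by camera, and adjusted p = 0.548 with an estimated correlation) and secreted proteins −0.053 (adjusted p = 0.0122, and adjusted p = 0.699 with an estimated correlation), with 0 members passing over either list alone. Beside them, stellate cell and fibroblast markers averaged −0.18 (camera adjusted p = 0.0717) and liver endothelial markers −0.17 (camera adjusted p = 0.163), and neither list was called. The secreted protein call was lost with library totals alone (mean −0.034, adjusted p = 0.136), with no filter on low counts (mean −0.037, adjusted p = 0.25), without TTR REVERSIR replicate 1 (mean −0.019, adjusted p = 0.588) or 3 (mean −0.046, adjusted p = 0.0638) and without siRNA + TTR REVERSIR replicate 2 (mean −0.033, adjusted p = 0.128) or 3 (mean −0.032, adjusted p = 0.317). The 95% interval was within 2-fold for 91.8% of genes.

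The interaction asks whether the effect of siRNA differs between the TTR and the scrambled sequence. For Ttr the difference was 2.04 ± 0.128 (95% interval 1.78 to 2.30, adjusted p = 3.28e-10), and no other gene passed in edgeR or DESeq2, with 601 at an unadjusted p under 0.05. Without the filter on low counts edgeR called 21. Genes with the next smallest p had values of 0.59 for Aldh1a1, 0.60 for Serpina7, 0.51 for Hif1a, −0.45 for Hgfac, −0.81 for Dpysl2, 0.83 for Tnip2, 0.81 for Gm14420, −0.73 for Gm13699 and −0.80 for Gm4737 (adjusted p = 0.889). Mitochondrially encoded mRNAs averaged 0.32 (adjusted p = 2.09e-05 by camera, and adjusted p = 0.548 with an estimated correlation) and secreted proteins −0.12 (adjusted p = 0.000581, and adjusted p = 0.564 with an estimated correlation), with 0 members passing over either list alone. Liver endothelial markers averaged −0.42 in the interaction and were not called (camera adjusted p = 0.151).

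Of the 18 lists, 10 were called by camera in none of the 12 comparisons. Their mean log2 fold changes ran from −0.062 to 0.085 for retinol and thyroid hormone handling, from −0.072 to 0.068 for RNA interference machinery and from −0.079 to 0.064 for the asialoglycoprotein receptor and endolysosome. They ran from −0.057 to 0.038 for cholesterol and fatty acid synthesis, from −0.056 to 0.013 for the peroxisome proliferator response and fatty acid oxidation, and from −0.083 to 0.083 for oxidative stress and heat shock. For the cell cycle the range was −0.17 to 0.13, for liver endothelial markers −0.42 to 0.35, for stellate cell and fibroblast markers −0.19 to 0.087 and for cholangiocyte markers −0.094 to 0.14. Camera made 23 calls in 216 tests of lists with the preset correlation and 0 with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, made 0. The mean, the median and the test had the same sign in each of the 23.

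The genes called in siRNA against PBS were followed into comparisons that share no library with it. The 113 higher genes had a median of 0.47 there and of 0.03 with siRNA + scrambled REVERSIR against scrambled REVERSIR, where 57.5% kept their sign. That value of 0.03 was at percentile 99.8 of 10000 random lists matched on expression (95% of them from −0.033 to 0.021), in the direction of siRNA against PBS, and camera did not call it (adjusted p = 0.254). With TTR REVERSIR present the median was −0.04, at percentile 0.05, and 34.5% kept their sign. Between siRNA + TTR REVERSIR and siRNA + scrambled REVERSIR it was 0.0028, at percentile 66.9. The 178 lower genes besides Ttr had a median of −0.38 with siRNA against PBS, and of −0.02, 0.0068 and 0.03 in the same 3 comparisons, with 59.6% of the same sign in the first, and at percentiles 13.7, 99.5 and 100 of their random lists, which treat genes as independent. Camera called 2 of these 6 tests (adjusted p = 0.0216 for both), the higher genes in siRNA + TTR REVERSIR against TTR REVERSIR and the lower genes in siRNA + TTR REVERSIR against siRNA + scrambled REVERSIR, each in the direction opposite to that in siRNA against PBS. In the second of these both groups had siRNA, so a reversal of siRNA effects by the TTR REVERSIR would also give the opposite direction. With an estimated correlation the 2 tests had p = 0.526 and 0.556.

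Since the guide of the siRNA is complementary to Ttr, each 7-base stretch of the Ttr mRNA was tested as a possible match to its seed in the 3' untranslated regions (UTRs) of 10545 genes. Of 1144 stretches, 798 were called in siRNA against PBS by rank-sum tests across genes, which are not independent replicates. The one with the smallest p among those with lower genes was TTTTAAA, at position 870 of the 1219 bases of the mRNA, carried by 4645 genes that lay −0.084 below the other 5900. In siRNA + scrambled REVERSIR against scrambled REVERSIR the same genes lay −0.038 below the others (n = 10545 genes, p = 6.11e-32), in siRNA + TTR REVERSIR against TTR REVERSIR 0.015 above (p = 1.04e-06), and in siRNA + TTR REVERSIR against siRNA + scrambled REVERSIR 0.0037 above (p = 0.651). The 3' UTRs with the match were 58.4% A and T, against 52.2% in the rest, and 0 stretches were called within classes of A and T content and length, where 98 had an unadjusted p under 0.05.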

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

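Of the tests below, those of Serpina7 with siRNA present, of A and T content and length of the 3' UTR, of the short match within classes of that content, and of the fold change left after GC correction were chosen only after the result was seen. The effect of siRNA on Ttr differed between the groups with the scrambled and with the TTR REVERSIR. The interaction term that tests this difference came to 2.04 ± 0.128 (adjusted p = 3.28e-10). No sample was compared with its own group for being far from the others, since groups of 3 are too small for that test.

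For the count of genes in the interaction, 6 of 100 splits of the 12 libraries, the real one included, gave at least the 1 gene of the real split, with 119 as the highest of the others. Chance is therefore not excluded for the count of 1, and this says nothing against Ttr itself, whose change is given by its own test.

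The genes besides Ttr that were called against PBS were weighed as an effect of the treatments and as a difference of PBS replicates 1 and 2. For 1360 genes called when siRNA was compared with PBS replicates 1 and 2 alone, PBS replicate 3 lay 0.02 from the 12 treated libraries outside that comparison and PBS replicates 1 and 2 lay 0.34 from them, so that its displacement was 6.17% of theirs (SD 10.8 over single treated libraries). The bounds set beforehand were over 75% for an effect of the treatments, and under 25% by 2 SD for a difference of 2 PBS libraries, which was narrowly missed. The genes were selected with PBS replicates 1 and 2 and without replicate 3, which enlarges the displacement of replicates 1 and 2. A true effect of the treatments could therefore also give under 75%. The 2 explanations cannot be told apart, because of this selection and because the test rests on 1 library. No test asked whether PBS replicate 3 or the other 2 carry the unusual values. The share of mitochondrial ribosomal RNA stays open too, since the slopes of genes on it within treated groups correlated with the difference between the PBS libraries at 0.0994, above 87 of 100 permutations (highest 0.147).

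GC content and transcript length were also tested as a source of the same calls, and the count in siRNA against PBS fell from 292 to 146 after correction, below the level set beforehand as a sign of this source. The 291 genes besides Ttr nevertheless kept a median of 82.2% of their log2 fold change, from 0.41 (median standard error 0.0993) to 0.35 (0.0951), which argues against it as the whole source. Of them 111 were still called. The 180 others went from 0.38 (0.0915) to 0.28 (0.0850), so these calls ended because the fold became smaller and not because the error grew. A part in the pattern stays open.

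With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Counts of splits given here and below include the real one. In siRNA against PBS 1 of the 10 splits, the real one itself, called as many as 292 genes, with 48 as the highest other. For siRNA + scrambled REVERSIR and siRNA + TTR REVERSIR against PBS this was also 1 of the 10 splits (68 with 42 as the highest other, and 88 with 18). For scrambled REVERSIR against PBS it was 3 splits (47, highest other 93) and for TTR REVERSIR against PBS 2 splits (78, highest other 731). The split with 731 genes set PBS replicates 1 and 2 and TTR REVERSIR replicate 2 against the rest, and the one with 93 set them and scrambled REVERSIR replicate 3 against the rest. In each of the 5 comparisons with PBS, every other split with over 10 genes kept PBS replicates 1 and 2 on one side, which points to a structure of the samples.

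Among comparisons without PBS, 1 of the 10 splits gave as many genes as the real one in siRNA + TTR REVERSIR against siRNA (1, highest other 0), siRNA + TTR REVERSIR against siRNA + scrambled REVERSIR (1, highest other 0), TTR REVERSIR against scrambled REVERSIR (2, highest other 0) and siRNA + scrambled REVERSIR against scrambled REVERSIR (2, highest other 1). All 10 splits did so in siRNA + scrambled REVERSIR against siRNA (0, highest other 0) and in siRNA + TTR REVERSIR against TTR REVERSIR (0, highest other 211), as a real count of 0 makes certain. These counts of 0 are by edgeR, with 415 and 495 genes at an unadjusted p under 0.05 (558 by chance) and 0 by DESeq2 in both. The split with 211 genes put TTR REVERSIR replicates 1 and 3 with siRNA + TTR REVERSIR replicate 1, which again points to a structure of the samples that the labels do not name.

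Serpina7 was higher with scrambled than with TTR REVERSIR, and the scrambled libraries were the shallowest on average. Thinned to the total of the shallowest library, the difference was −0.65 ± 0.113 as a median of 20 thinnings, 18 of which passed. Random thinning keeps the expected ratio of counts, so the fold had to stay near its value. This test therefore cannot decide on low depth of the scrambled libraries. It shows only that the call mostly held with the counting error of equal depth. If the scrambled sequence raised Serpina7 whether or not siRNA was present, siRNA + scrambled REVERSIR would lie above siRNA, and it lay at −0.37 ± 0.103. An effect of the scrambled sequence in the absence of siRNA alone may remain as a hypothesis, as does a property of these cultures. At log2 fold changes between −0.65 and −0.59 the call was lost without scrambled REVERSIR replicate 2 (adjusted p = 0.284) or 3 (adjusted p = 0.138) and without TTR REVERSIR replicate 1 (adjusted p = 0.368) or 3 (adjusted p = 0.285).

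Genes with TTTTAAA in the 3' UTR were lower after siRNA, which was weighed as repression through the seed of the guide and as an effect of the base content of the UTR. In siRNA + scrambled REVERSIR against scrambled REVERSIR these genes were also lower (−0.038), which had been set beforehand as a sign of repression. Within classes of A and T content and length that shift was 0.00573 ± 0.00352, which argues against repression through this match, since the bound written beforehand did not allow for base content. In siRNA against PBS 2.85% ± 5.59 of the shift was left within the classes, as A and T content and length together would give. With genes matched on 3' UTR length alone the shift was −0.079, against −0.084 unmatched, which argues against length alone. Why genes with much A and T in the UTR were lower was not tested, and the true guide sequence was not used here.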

How the results depend on the processing

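The runs without PBS replicates 1 and 2 together, with the share of mitochondrial ribosomal RNA as a covariate, without ribosomal RNA genes and Lars2, with GC and length correction, and within classes of A and T content were chosen only after the result was seen. Ttr kept its side of the threshold in 78 of 78 runs without 1 library and in 120 of 121 other runs, the exception being TTR REVERSIR against PBS with library totals alone (0.47, adjusted p = 0.0254). Its direction held where it was called. Where it was not called, its sign turned in scrambled REVERSIR against PBS (−0.041 to 0.079 without 1 library, −0.13 to 0.27 in other runs) and in siRNA + TTR REVERSIR against PBS (−0.24 to 0.22 in other runs). Over the other runs it lay between −2.34 and −1.90 in siRNA against PBS, 2.11 and 2.13 in siRNA + TTR REVERSIR against siRNA, and 2.03 and 2.04 in the interaction. Without 1 library these were −2.24 to −2.12, 2.03 to 2.17 and 1.94 to 2.10. Counts of genes stayed within 1.5 times in 38 of 78 runs without 1 library and 75 of 121 others. Side of the threshold, and direction where called, were kept by gene lists in 1330 of 1404 and 2060 of 2157 runs, by single genes in 503 of 1038 and 1113 of 1630, by siRNA-changed genes in 53 of 72 and 43 of 54, and by short matches in 20 of 25. Depth and the number of libraries limit what could be seen, as 40% of simulated changes of 0.5 were recovered in siRNA against PBS and the 95% interval of the interaction lay within 2-fold for 79.2% of genes. Except where stated, the cause was not tested.

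Counts against PBS follow in the order siRNA, scrambled REVERSIR, TTR REVERSIR, siRNA + scrambled REVERSIR and siRNA + TTR REVERSIR. Library totals alone, which shift all genes, gave 3844, 1580, 2883, 3557 and 4089. Fits with no filter on low counts gave 677, 424, 498, 564 and 585. These fits lowered p-values at nearly the same fold, as for Serpina7 above. Their counts, here and in comparisons without PBS, are therefore not comparable with the others. Without PBS replicates 1 and 2 together, which leaves 1 control, the called genes besides Ttr had median sizes of 0.20, 0.26, 0.26, 0.24 and 0.24 on the log2 scale. With all 3 controls these sizes were 0.41, 0.52, 0.58, 0.56 and 0.53. The mitochondrial rRNA share as a covariate gave 1, 1, 0, 2 and 3. PBS replicates 1 and 2 held 24.3% and 24.1%, against 1.69% to 9.56% in the other 16 libraries. The covariate thus takes up part of any difference from PBS, and calls lost with it do not show that the share was their cause. The fit of the compared groups only, which takes the spread from those groups alone, gave 1, 7, 0, 7 and 1. It has fewer libraries, and counts in comparisons without PBS, from 0 to 2 in the fit reported, were too low to show a loss from this. There it gave 4 against 2 in TTR REVERSIR against scrambled REVERSIR, and 5 against 2 in siRNA + scrambled REVERSIR against scrambled REVERSIR. Most calls against PBS were thus made only with a spread pooled over all groups. Whether fewer libraries or the spread of the compared groups lowered the counts against PBS cannot be told. DESeq2 gave 188, 173, 201 and 242 for the last 4. GC content and length correction gave 146 for siRNA, and with ribosomal RNA genes and Lars2 left out siRNA + scrambled REVERSIR had 107. Each 0 is by edgeR.

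In comparisons without PBS, fits with no filter on low counts called 21 genes in siRNA + TTR REVERSIR against siRNA, 33 in siRNA + scrambled REVERSIR against siRNA, 35 in siRNA + TTR REVERSIR against siRNA + scrambled REVERSIR, 42 in TTR REVERSIR against scrambled REVERSIR, 41 in siRNA + scrambled REVERSIR against scrambled REVERSIR, 35 in siRNA + TTR REVERSIR against TTR REVERSIR and 21 in the interaction. DESeq2 called 15 in the first. Library totals alone gave 0 by edgeR in TTR REVERSIR against scrambled REVERSIR and 1 in siRNA + scrambled REVERSIR against scrambled REVERSIR, where the fit of the compared groups only gave 4 and 5. In siRNA + TTR REVERSIR against TTR REVERSIR that fit and the mitochondrial rRNA share as a covariate each gave 1.

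The labels do not say whether replicate numbers pair samples. Deviations from the group means had a mean correlation of 0.00116 over 45 pairs of the same number (−0.148 to 0.287), 6 of them over 0.1. By these deviations, 6 of 18 libraries were closest to their own number. No general pairing by number was seen, but pairing of some samples is not excluded. The replicate block gave 47 genes in siRNA + TTR REVERSIR against PBS, and counts within 1.5 times elsewhere.

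Without 1 library, counts ranged from 1 to 1365, 0 to 749, 0 to 978, 1 to 1142 and 0 to 1151 in the 5 comparisons with PBS, with the highest each time without PBS replicate 3. They ranged from 1 to 2 in siRNA + TTR REVERSIR against siRNA, 0 to 5 in TTR REVERSIR against scrambled REVERSIR and 1 to 9 in siRNA + scrambled REVERSIR against scrambled REVERSIR.

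With library totals alone, list means turned to 0.20 for secreted proteins and 0.21 for xenobiotic metabolism in scrambled REVERSIR against PBS. They turned to 0.12 for mitochondrially encoded mRNAs in siRNA + scrambled REVERSIR against PBS. The median of all genes moved by 0.29 and 0.32 in these comparisons, so the means stayed below it and the turn of sign goes with the scale. With no filter the xenobiotic list turned to 0.0121 in the interaction.

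For genes higher with siRNA, the median in siRNA + TTR REVERSIR against TTR REVERSIR was 0.00166 with library totals alone, −0.00788 with no filter, −0.033 with a replicate block, −0.0402 without PBS replicates 1 and 2 together and 0.00703 with the mitochondrial covariate, and −0.101 to 0.0279 without 1 library, turning above 0 without TTR REVERSIR replicate 1 (0.0279) and siRNA + TTR REVERSIR replicate 2 (0.00204). In siRNA + scrambled REVERSIR against scrambled REVERSIR it was 0.0538 with no filter, and between the 2 groups with siRNA and an oligonucleotide −0.0684 (without siRNA + TTR REVERSIR replicate 1) to 0.0242 without 1 library. For the lower genes the first of these was 0.0086 with no filter and −0.0308 to 0.0452 without 1 library, the second −0.00054 with no filter, −0.0497 without PBS replicates 1 and 2 together and −0.0733 to −0.0038 without 1 library, and the last 0.0524 with library totals alone, 0.013 with no filter and 0.0131 to 0.154 without 1 library. These genes were selected anew in each run. Where too few genes passed, those with the smallest p in each direction were used instead. This was so without PBS replicates 1 and 2 together, without PBS replicate 1 or 2 alone, and with the mitochondrial covariate. The medians of these runs are therefore not of genes past the threshold. A fit of the compared groups only was not run for them, as it holds 1 comparison at a time. That fit gave no value for 3 of 216 list tests.

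Within strata of 3' UTR AT content and length, 0 stretches passed by rank-sum tests (98 at an unadjusted p under 0.05), and another stretch, selected there, had shifts of −0.0252, 0.0011 and −0.00028 in siRNA against PBS and with scrambled and TTR REVERSIR. With 6-mers the shift between the 2 groups with siRNA and an oligonucleotide was 0.0073 (n = 10545 genes, p = 0.00592). Matched on 3' UTR length, 612 stretches of 7 bases passed, 307 with lower and 305 with higher genes. Unmatched, 731 had lower and 67 higher genes.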

Other observations

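Members of lists with no gene past the threshold in siRNA against PBS had the following log2 fold changes there, given for up to 2 members with the smallest p. Acute phase genes were at 0.30 ± 0.0894 for haptoglobin (Hp, adjusted p = 0.0663) and 0.40 ± 0.120 for Saa2. The asialoglycoprotein receptor subunit gene Asgr1, which serves the uptake of GalNAc conjugates, was at 0.28 ± 0.0916 (adjusted p = 0.0883) and the endosomal Rab7 at −0.36 ± 0.115. Of the cholesterol and fatty acid synthesis list Stard4 was at −0.40 ± 0.151, in fatty acid use Angptl4 at 0.35 ± 0.112 and Acadl at −0.56 ± 0.190, and in the cell cycle list Ccne2 at −0.59 ± 0.179 and Mcm2 at 0.36 ± 0.182. Among markers of other liver cells, Mpeg1 and C1qb of macrophages were at 0.35 ± 0.112 and 1.12 ± 0.398, Oit3 and Cdh5 of endothelium at 0.62 ± 0.267 and −0.50 ± 0.460, Reln and Vim of stellate cells and fibroblasts at −0.28 ± 0.0802 and 0.20 ± 0.0867, and Spp1 and Sox9 of cholangiocytes at 1.75 ± 0.509 and −0.62 ± 0.287. None of these genes passed in edgeR, which called 292 genes in this comparison and had 2241 at an unadjusted p under 0.05, where DESeq2 called 421.

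Protein-coding genes held 73.9% and 72.9% of counts in PBS replicates 1 and 2 and 91.3% in PBS replicate 3. Lars2, the mitochondrial leucyl-tRNA synthetase, held 4.71% and 4.76% in the first and second and 0.0854% in the third. It also held 3.79% and 3.60% in scrambled REVERSIR replicates 2 and 3, against 0.0101% in replicate 1. The non-coding transcript AY036118 held 0.000489% and 0.00171% in PBS replicates 1 and 2, 1.51% in PBS replicate 3, 1.75% in scrambled REVERSIR replicate 1, and 0.00922% and 0.00718% in scrambled REVERSIR replicates 2 and 3. Lars2 and AY036118 were among the genes left out in the run without ribosomal RNA genes. Whether the reads counted for them come from their own transcripts was not tested, so these shares are not a measure of Lars2 mRNA.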
